A study of Mus musculus with 6 samples.

How the data were processed

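Messenger RNA was measured in 6 libraries of Ba/F3, a mouse haematopoietic cell line that normally depends on interleukin-3, with 3 libraries of cells carrying an empty vector and 3 of cells expressing the TPR-FGFR1 fusion. Per the labels' protocols, each library was made from 1 µg of total RNA with a stranded Illumina mRNA kit and sequenced as read pairs on a NovaSeq X Plus. The design text describes lentiviral infection and 6 days of selection in puromycin at 5 µg/ml for the fusion cells. It does not state whether the empty vector cells were selected in the same way. No label states whether the cells were kept in interleukin-3, whether the fusion sequence is human or mouse, or whether the replicates came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

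The authors deposited a table of TPM values, a length-scaled measure of transcript abundance, for 57010 Ensembl gene IDs, and each library's column sums to 1e+06 within rounding. TPM is also scaled by each library's own total, and the deposited values hold at most 2 decimals. Per the submitters' processing notes, fastp, HISAT2, StringTie and the mouse build GRCm39 were used. Their versions, the annotation release and the strand setting are not given in the sources used here. TPM keeps no read number, so the depth is unknown and no counting interval or floor was computed. The columns were matched to samples by their names (EV for empty vector and OE for the overexpressing cells, with the replicate number), and 0 columns of other samples were present.

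Gene symbols, biotypes, and the GC content and length of each gene's longest transcript were taken from GENCODE M21, which is built on the earlier build GRCm38. For that reason the IDs were matched by name and no coordinates are given. A symbol was found for 52029 IDs (91.3%), and for 12541 of the tested genes (97.5%). Where a symbol belonged to several IDs, the most abundant ID kept it.

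Values were analysed as log2(TPM + 1) for the 12862 genes with a mean of at least 1 TPM over the 6 libraries. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level), with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes of low level. Fgfr1 and Tpr were also compared by a two-sided exact permutation test of the 6 log2(TPM + 1) values. Fgfr1 lies under the filter, so its limma values come from a fit in which Fgfr1 was added to the tested genes.

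Before the data were examined, 32 gene lists were fixed: the fusion partners, pathways of FGF receptor, MAPK, STAT5 and FOXO signalling, proliferation, stress and metabolism, immune genes, chromatin regulators, markers of haematopoietic and packaging cells, and mitochondrially encoded genes. The 28 lists of pathways and markers with at least 5 tested members were tested with limma's camera at a correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list moved more than the other tested genes, while fry asks only whether its members moved. For each list, the median was also set against 10000 random lists, each member being replaced by 1 of its 200 nearest tested genes in level, GC content and length. The named genes also follow a rule fixed then. They are Fgfr1 and Tpr, and the 10 largest rises and 10 largest falls among called genes with groups that do not overlap and a mean of at least 5 TPM in the higher group. They also include up to 4 members of smallest adjusted p for each list with a camera call or at least 3 called members, and 15 further genes of FGF receptor, cytokine and B-cell biology. Predicted genes named Gm or ending in Rik and antigen receptor segments were left out of the largest changes. Genes outside that rule are said to be so where they appear.

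The alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, 3 other scalings, eBayes without trend or with robust settings, library weights (arrayWeights), the replicate number as a block, and leaving out each library. Chosen after the data were seen were a correction for GC content and length, the same correction without TPR-FGFR1 replicate 3, and a fit of protein-coding genes alone. Gene families were also chosen then by symbol and are described by counts alone, without a test. The correction removed from each library a smooth trend of its deviations from the gene means over GC content and length (splines with 4 degrees of freedom). The 321 tested genes without a GC value were left out of it. The pipeline was tested on simulated data with the spread of the real libraries and 12869 genes tested. It recovered 45.5% of genes changed 1.5-fold, 78.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 19 false calls among 175. With a GC trend added to 2 fusion libraries, 66.7% of the genes changed 2-fold were recovered with 12 false calls among 151, and after the correction 85% with 6 among 161. Simulated genes varied independently, and the trend was added to a spread that already held the real one. These numbers therefore do not show how many false calls the real trend gives. Within groups, libraries correlated at r = 0.962 to 0.978 over the tested genes, and at least 98.3% of the genes differed in value between any pair, so all 6 were kept as separate samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.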

Results

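The series compared gene expression in Ba/F3 cells carrying the TPR-FGFR1 fusion with that in cells carrying an empty vector, with 3 libraries in each of 2 groups. Ba/F3 is an interleukin-3 dependent mouse line used to study oncogenic kinases, and its cells are labelled as B lymphocytes. TPR is a coiled-coil protein of the nuclear pore basket, and FGFR1 is a receptor tyrosine kinase for fibroblast growth factors. The deposited values are TPM, so the sequencing depth of each library is unknown. Between 12679 and 12839 genes reached 1 TPM in each library. Mitochondrially encoded transcripts made up 11.4% to 15.4% of TPM, most of it from mt-Atp8 (7.52% to 9.94%).

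Fgfr1 (ENSMUSG00000031565) was higher in every TPR-FGFR1 library than in any empty vector library. It averaged 0.847 ± 0.363 TPM (SD, n = 3) with the fusion against 0.0367 ± 0.0153 TPM (SD, n = 3) with the empty vector, a 23.1-fold difference at a low level. The Fgfr1 log2 fold change was 0.82 (SE 0.213, limma adjusted p = 0.0397), and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The adjusted p was above 0.05 without any 1 of the 6 libraries (0.0515 to 0.113) and in 10 of 20 alternative settings in all, over which it ran from 0.00110 to 0.443. The labels do not state whether the fusion sequence is human or mouse, so the values count only what was assigned to the mouse gene. Tpr (ENSMUSG00000006005) stood at 148 ± 6.52 TPM (SD, n = 3) with the empty vector and 138 ± 11 TPM (SD, n = 3) with the fusion. Its log2 fold change was −0.10 (SE 0.0855, limma adjusted p = 0.399, two-sided exact permutation p = 0.4). After correction for GC content and length it was −0.28, with an adjusted p of 0.00841.

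Across the transcriptome, 2600 of 12862 tested genes changed (20.2%), of which 1309 rose and 1291 fell in the fusion cells. Of these, 235 changed at least 2-fold, with 70 rises and 165 falls. The largest rises included Ccni, which encodes cyclin I, from 47.4 ± 3.54 to 146 ± 16.2 TPM (SD, n = 3 per group, log2 fold change 1.6, adjusted p = 0.00225). The zinc importer gene Slc39a10 rose from 3.75 ± 0.261 to 11.6 ± 2.29 TPM. Also among the 10 largest rises were Zfp143 and Sp4, which encode transcription factors (log2 fold changes 1.29 and 1.23), Idh1, which encodes the cytosolic isocitrate dehydrogenase (1.21), Cnbd2 (1.33), Caprin2 (1.17), Gtdc1 (1.17), Aph1c (1.16) and Tpmt (1.15). The largest falls were in the histone genes Hist1h2bg (log2 fold change −3.40) and Hist1h1c, the latter from 15.1 ± 0.856 to 1.67 ± 0.574 TPM. The main transcripts of such histone genes have no poly(A) tail, so values from an mRNA kit may not follow their level. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, fell from 240 ± 5.42 to 48.4 ± 8.64 TPM (log2 fold change −2.30, adjusted p = 0.00221). Oas2, an interferon-induced gene, fell from 27.0 ± 0.996 to 6.77 ± 0.494 TPM. Mt2, a metallothionein gene, Lyl1, a haematopoietic transcription factor gene, and Mif, a cytokine gene, fell by 2.02, 2.02 and 2.18 on the log2 scale. Ptprcap and the pro-apoptotic gene Bbc3 fell by 1.95 and 1.87. Srp54b fell by 2.14, but it has near-identical copies among which reads may have been split, as have the histone genes. The call was lost in 9 of 20 alternative settings for Bbc3 and Srp54b, 7 for Mif, 6 for Ptprcap, 5 for Mt2 and 4 for Lyl1, and the Bbc3 log2 fold change ran from −2.43 to −1.15.

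Groups did not overlap for 5580 tested genes (43.4%, against 10% by chance). Genes that fell were richer in GC (median 53.7%) than genes that rose (45.4%) or were not called (48.7%). With the tested genes ordered by GC content into 5 equal bins, 35 rose and 547 fell in the highest bin, and 402 rose and 68 fell in the lowest. The median log2 difference from the empty vector mean in the highest bin, minus that in the lowest, was −0.694 and −0.861 in TPR-FGFR1 replicates 1 and 2, and −0.0694 in replicate 3. Over all tested genes, replicate 3 correlated with the empty vector libraries at r = 0.9657 to 0.9661, and with TPR-FGFR1 replicates 1 and 2 at r = 0.9635 and 0.962. The count of changed genes was 3986 after correction for GC content and length, 1146 without the filter on low values and 6396 without TPR-FGFR1 replicate 3. It was between 220 and 869 without any other library. The main calls were kept in the same direction after the correction for 2203 of 2556 genes.

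**Figure D1:**
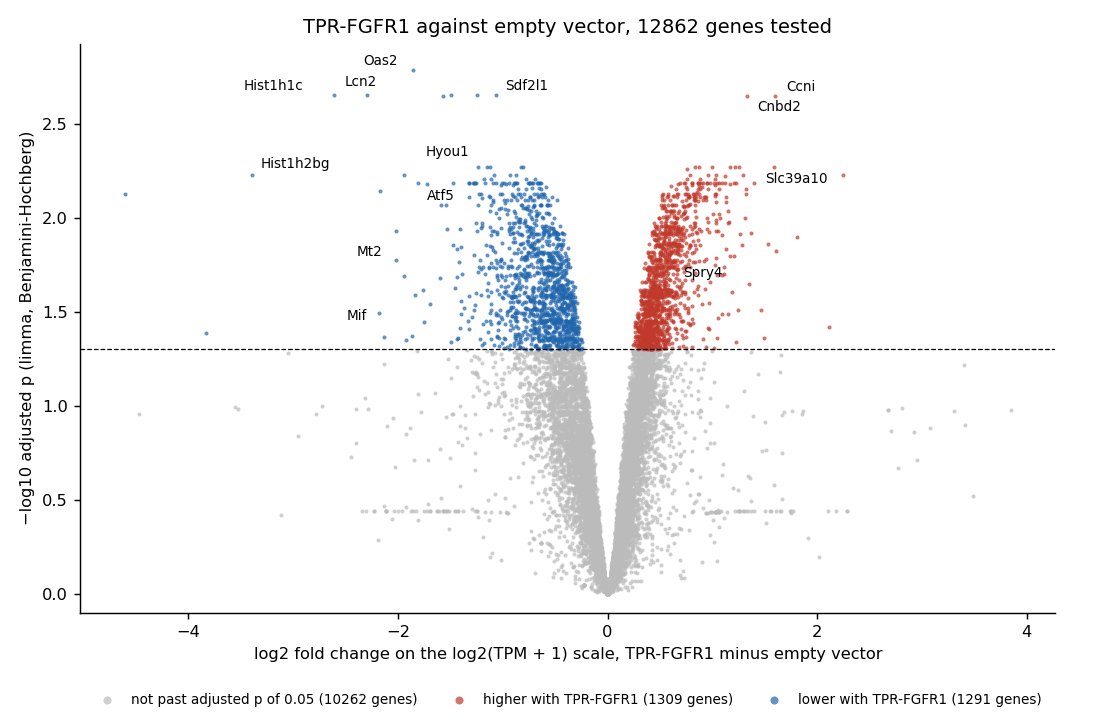
Each point is 1 of 12862 tested genes, with the log2 fold change of TPR-FGFR1 over empty vector on the x axis and −log10 of the limma adjusted p on the y axis. Above the dashed line at an adjusted p of 0.05, 1309 genes were higher (red) and 1291 lower (blue) in the fusion cells, and Ccni, Lcn2 and Oas2 are among those named.

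**Figure D2:**
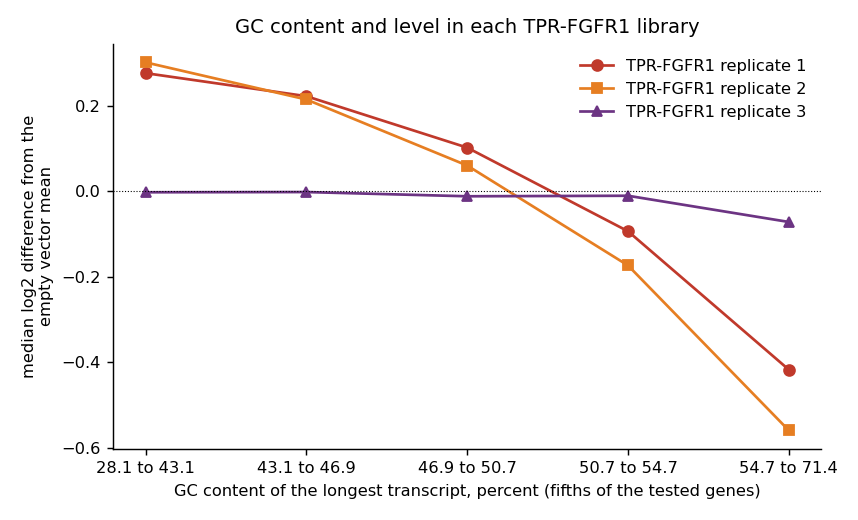
Median log2 difference of each TPR-FGFR1 library from the empty vector mean (y axis) in 5 equal bins of the tested genes ordered by the GC content of the longest transcript (x axis, percent). Replicates 1 and 2 run from 0.276 and 0.302 in the lowest bin to −0.417 and −0.559 in the highest, and replicate 3 from −0.00224 to −0.0717.

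Genes of the unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, fell together. Of 18 tested members, 14 fell and 0 rose, with 15 falls when adjusted over the list alone. Hyou1, a chaperone gene of the endoplasmic reticulum, fell from 139 ± 3.51 to 62.1 ± 6.76 TPM (SD, n = 3 per group, adjusted p = 0.00532). Herpud1, whose product acts in the degradation of misfolded proteins there, fell from 190 ± 11.2 to 87.3 ± 8.61 TPM, and Sdf2l1 and Dnajb11 fell by 1.07 and 0.78 on the log2 scale. The median log2 fold change of the list was −0.57, and its medians in the 3 TPR-FGFR1 libraries were −0.53, −0.50 and −0.72. Camera called the list at an adjusted p of 1.08e-09, and the adjusted p = 0.312 with an estimated correlation. After correction for GC content and length 15 members fell, and leaving out each library in turn gave 7 to 17 falls.

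A second stress-related group, the ATF4 and amino acid response genes, moved the same way, with 14 of 21 members falling, 0 rising, and 17 falls when adjusted over the list alone. The transcription factor gene Atf5 fell from 50.9 ± 4.06 to 14.2 ± 4.02 TPM (SD, n = 3 per group). Slc7a11, the cystine transporter gene, fell from 17.8 ± 0.232 to 7.74 ± 1.04 TPM, and the arginine transporter gene Slc7a1 fell from 109 ± 2.43 to 72.7 ± 2.22 TPM. Mthfd2, which encodes a mitochondrial folate enzyme, fell by 0.64 on the log2 scale. The median log2 fold change was −0.57, and library medians were −0.55, −0.69 and −0.39. Camera gave an adjusted p of 4.15e-07, and the adjusted p = 0.478 with an estimated correlation. After correction for GC content and length 14 members fell, with a median of −0.35. Leaving out each library in turn gave 5 to 18 falls, with 5 without any empty vector replicate.

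Interferon response genes were also lower in the fusion cells, with 11 of 23 falling and 0 rising, both over all genes and adjusted over the list alone. Besides Oas2, Mx2, whose biotype is polymorphic pseudogene, fell from 3.37 ± 0.711 to 0.843 ± 0.1 TPM (SD, n = 3 per group). Irf9, part of the factor that drives interferon-stimulated genes, fell from 14.7 ± 0.863 to 8.54 ± 0.626 TPM. Oas3 fell by 0.71 on the log2 scale. Camera gave an adjusted p of 2.43e-05, and the adjusted p = 0.22 with an estimated correlation. Library medians were −0.56, −0.60 and −0.30. After correction for GC content and length 14 members fell. Leaving out each library in turn gave 2 to 13 falls, with 3, 2 and 3 without empty vector replicates 1, 2 and 3, and 3 rises only without TPR-FGFR1 replicate 3.

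**Figure D3:**
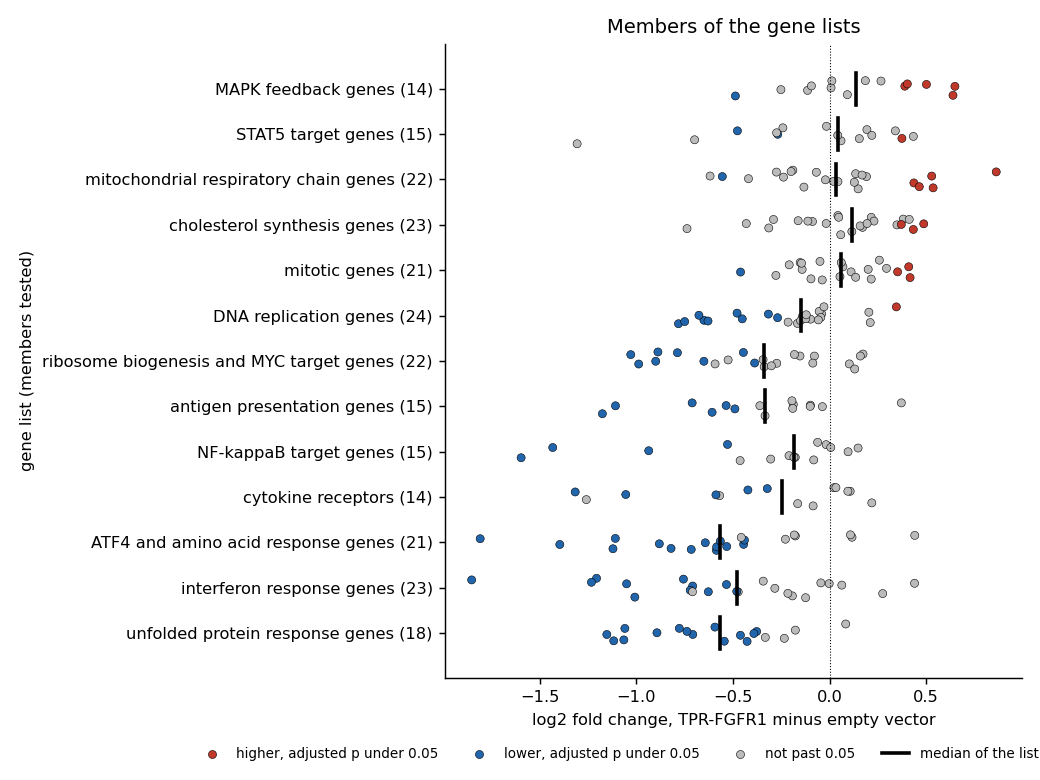
Log2 fold change (x axis) of each tested member of 13 gene lists (y axis, number tested in brackets), with called rises in red, called falls in blue, other members in grey and the list median as a bar. The medians of the unfolded protein response, ATF4 and interferon lists lie at −0.57, −0.57 and −0.48, and that of the MAPK feedback genes at 0.14.

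In the MAPK feedback list, which holds genes that MAPK signalling induces, 5 of 14 rose and 1 fell, with the same numbers when adjusted over the list alone. Spred1 rose from 30.2 ± 0.628 to 48.1 ± 6.08 TPM, Spry4 from 1.5 ± 0.206 to 2.88 ± 0.00577 TPM and Etv5 from 6.38 ± 0.545 to 9.42 ± 0.140 TPM (SD, n = 3 per group). The phosphatase gene Dusp2 fell by 0.49 on the log2 scale, but its log2 fold change was −0.03 (adjusted p = 0.848) after correction for GC content and length. Dusp6, a feedback phosphatase of ERK, stood at 37.7 ± 4.39 and 40.2 ± 4.34 TPM (adjusted p = 0.596). The list was not called by camera (adjusted p = 0.144), while fry called it higher (0.016) and the adjusted p = 0.5 with an estimated correlation in camera. Leaving out each library in turn gave 0 to 5 rises and 0 to 3 falls, and camera gave an adjusted p of 0.601 without TPR-FGFR1 replicate 3. The calls of Spry4, Etv5 and Spred1 were lost in 7, 6 and 4 of 20 settings. After the correction 7 members rose, 0 fell, and camera gave an adjusted p of 0.00630, and the adjusted p = 0.434 with an estimated correlation. Of 18 immediate early genes, 1 rose and 5 fell (7 falls when adjusted over the list alone, camera adjusted p = 0.0519), among them Fos, from 127 ± 4.73 to 85.8 ± 9.09 TPM, and Klf6. Camera called that list in 7 of 20 alternative settings, with 11 falls and an adjusted p of 0.0173 without TPR-FGFR1 replicate 3, but gave 0.482 with a median of −0.10 after correction for GC content and length. Over all 6 libraries the adjusted p = 0.5 with an estimated correlation. Egr1 was under the filter, at 0.307 ± 0.0231 and 0.257 ± 0.0833 TPM. Of 9 tested FGF receptor family and adaptor genes, 1 rose and 1 fell.

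Genes of DNA replication fell more often than they rose, with 9 of 24 falling and 1 rising, and the same numbers when adjusted over the list alone. Tyms, the thymidylate synthase gene, fell from 59.1 ± 5.59 to 35.0 ± 6.04 TPM (SD, n = 3 per group), and Gins1, Rrm2 and E2f1 fell by 0.68, 0.45 and 0.63 on the log2 scale. After correction for GC content and length, Tyms, Gins1, Rrm2 and E2f1 had log2 fold changes of −0.83, −0.84, −0.56 and −0.28. In the same order, their calls were lost in 5, 0, 6 and 7 of 20 settings. Camera gave an adjusted p of 0.00494, and the adjusted p = 0.478 with an estimated correlation. Ribosome biogenesis and MYC target genes had 8 falls and 0 rises among 22 members (11 falls when adjusted over the list alone). The nucleolar genes Mybbp1a and Bop1 fell from 96.0 ± 3.21 to 51.2 ± 6.49 and from 24.6 ± 1.27 to 13.1 ± 3.15 TPM, and Srm and Fbl fell by 1.03 and 0.79 on the log2 scale. After correction for GC content and length, Mybbp1a, Bop1, Srm and Fbl had log2 fold changes of −0.75, −0.53, −0.53 and −0.69. Camera gave an adjusted p of 0.000453, and the adjusted p = 0.22 with an estimated correlation. With GC and length trends removed these lists had 14 and 13 falls, and leaving out each library in turn gave 1 to 10 and 2 to 13. Myc itself stood at 113 ± 8.30 and 112 ± 10.1 TPM (adjusted p = 0.912). Of 21 mitotic genes 3 rose and 1 fell (0 to 7 rises and 0 to 4 falls leaving out each library), the rises including Mki67 and Nusap1, whose calls were each lost in 8 of 20 settings. Of 24 cytosolic ribosomal protein genes 1 rose and 1 fell (0 and 0 when adjusted over the list alone, camera adjusted p = 0.0582). Camera called that list in 5 of 20 alternative settings, among them that without TPR-FGFR1 replicate 3, with 15 falls and 3 rises (adjusted p = 0.00134), and over all 6 libraries the adjusted p = 0.5 with an estimated correlation.

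Antigen presentation and NF-κB lists were called lower, the first in all but 2 of 20 alternative settings, both with the correction for GC content and length, and the NF-κB list in all but 7, which also included a filter at 5 TPM (camera adjusted p = 0.0791) and quantile normalization (0.0537). Of 15 antigen presentation genes 6 fell and 0 rose (7 falls and 1 rise when adjusted over the list alone), including the peptide transporter genes Tap1, from 66.8 ± 2.23 to 40.9 ± 7.98 TPM, and Tap2. The list medians in TPR-FGFR1 replicates 1, 2 and 3 were −0.32, −0.56 and −0.09, and leaving out each library in turn gave 0 to 12 falls, with 0 without any empty vector replicate and 12 without TPR-FGFR1 replicate 3. Camera gave an adjusted p of 0.00580, then 0.293 after the correction, and the adjusted p = 0.5 with an estimated correlation. Of 15 NF-κB target genes 4 fell and 0 rose, over all genes and adjusted over the list alone, among them Ltb, from 52.5 ± 2.00 to 19.8 ± 8.37 TPM, Ccl3 and Nfkb1. The list medians in the same libraries were −0.25, −0.26 and −0.02, and leaving out each library gave 0 to 7 falls. Camera gave an adjusted p of 0.0333, then 0.395 after the correction, and the adjusted p = 0.5 with an estimated correlation.

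Cytokine signalling genes moved in part. Of 14 cytokine receptor genes 5 fell and 0 rose (7 falls when adjusted over the list alone, camera adjusted p = 0.0519, fry 0.0255). Camera called that list in 5 of 20 alternative settings, and the adjusted p = 0.478 with an estimated correlation. Il3ra, the interleukin-3 receptor alpha chain, fell from 8.76 ± 3.38 to 2.89 ± 1.19 TPM (SD, n = 3 per group, adjusted p = 0.0259), a call lost in 6 of 20 settings, with adjusted p-values up to 0.0967. Its log2 fold change was −1.32, and −0.84 after correction for GC content and length. Csf2rb2 fell by 0.32 on the log2 scale, while Csf2rb, the common beta chain, stood at 229 ± 13.3 and 157 ± 39.1 TPM (adjusted p = 0.0522), and was called lower in 8 of 20 settings, one being the correction for GC content and length (log2 fold change −0.40, adjusted p = 0.0373). Of 15 cytokine and chemokine genes 4 fell (camera adjusted p = 0.0582, fry 0.038). Camera called that list in 2 of 20 settings, with arrayWeights (0.0325) and without empty vector replicate 2 (0.0438), and the adjusted p = 0.478 with an estimated correlation. Of 15 STAT5 target genes 1 rose and 2 fell (2 and 3 when adjusted over the list alone, camera adjusted p = 0.844). The STAT5 targets Cish (117 ± 1.31 and 131 ± 21.3 TPM), Pim1 (581 ± 6.18 and 607 ± 61.3 TPM) and Socs2 (17.1 ± 1.03 and 23.6 ± 3.73 TPM) did not pass the test, with adjusted p-values of 0.361, 0.663 and 0.0536. All 3 passed it after correction for GC content and length, with log2 fold changes of 0.28, 0.31 and 0.32 and adjusted p-values of 0.0283, 0.00452 and 0.0188, and 6 members of the list rose and 1 fell (camera adjusted p = 0.293). Mcl1, an anti-apoptotic gene in the STAT5 and BCL2 family lists, rose from 83.8 ± 4.58 to 109 ± 12.5 TPM, a call lost in 8 of 20 settings. Of 14 BCL2 family genes 1 rose and 2 fell, of 13 FOXO targets 2 rose and 3 fell, and of 16 p53 targets 3 rose and 5 fell, the last with 6 rises and 6 falls when adjusted over the list alone. Leaving out each library in turn gave 0 to 3 rises and 0 to 6 falls for the BCL2 family, 0 to 4 and 0 to 5 for FOXO targets, and 0 to 6 and 0 to 7 for p53 targets.

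**Figure D4:**
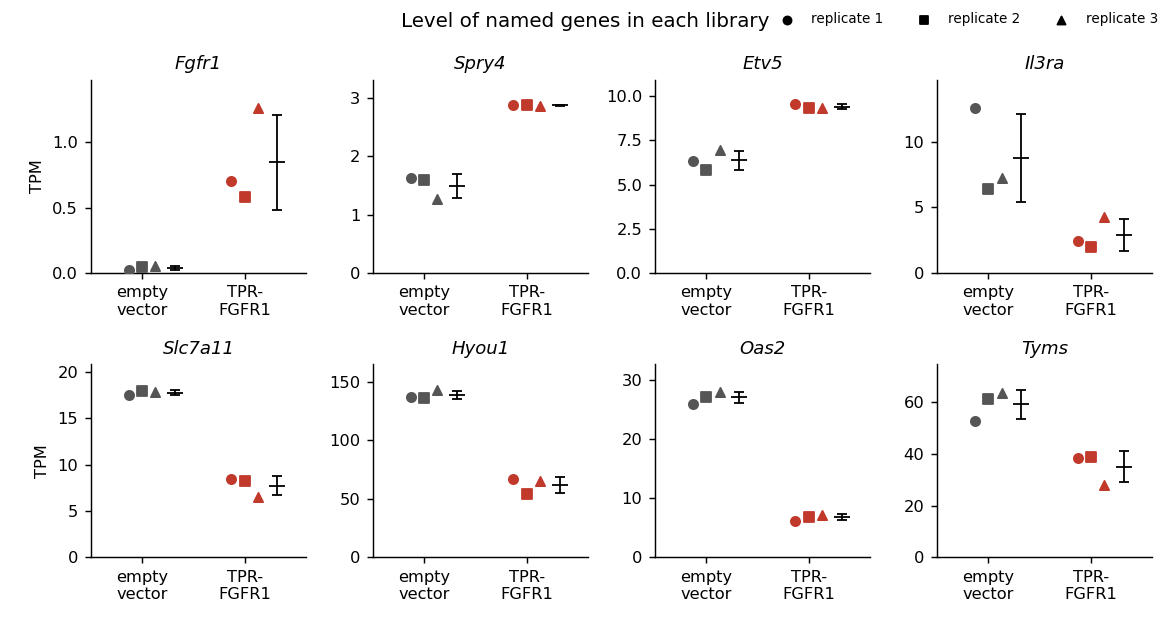
TPM (y axis, from 0) of 8 genes in each library, with replicates 1, 2 and 3 as circles, squares and triangles, and the mean with its SD (n = 3) beside each group. Fgfr1 is higher in all TPR-FGFR1 libraries, at 0.58 to 1.26 TPM against 0.02 to 0.05, as are Spry4 and Etv5, while Il3ra, Slc7a11, Hyou1, Oas2 and Tyms are lower.

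Metabolic lists were not called by camera, while fry called the cholesterol synthesis (adjusted p = 0.038) and respiratory chain genes (0.0215) higher, with medians of 0.11 and 0.03. In camera, the adjusted p = 0.5 with an estimated correlation for the first and 0.636 for the other. Of 20 glycolysis genes 2 rose and 5 fell (0 to 4 rises and 1 to 8 falls leaving out each library in turn). Pfkl, a phosphofructokinase gene, fell from 20.8 ± 0.492 to 7.87 ± 2.19 TPM and Aldoa, the aldolase gene, from 296 ± 8.72 to 148 ± 33.9 TPM (SD, n = 3 per group), while Pfkfb3, an activator of phosphofructokinase, rose from 16.5 ± 1.64 to 25.9 ± 1.13 TPM. Correction for GC content and length took the log2 fold changes of Pfkl and Aldoa from −1.33 and −1.02 to −1.03 and −0.65. That of Pfkfb3 was 0.62 before it and 0.63 after. Of 16 hypoxia response genes 3 rose and 3 fell (0 to 8 and 1 to 4 leaving out each library), the falls including the glucose transporter gene Slc2a1, from 18.3 ± 2.06 to 7.55 ± 3.20 TPM, a call lost in 6 of 20 alternative settings. Of 22 respiratory chain genes 5 rose and 1 fell (1 to 8 and 0 to 6 leaving out each library), with Cox5a rising from 93.0 ± 2.20 to 170 ± 18.2 TPM. Of 23 cholesterol synthesis genes 3 rose, including Hmgcs1, and 0 fell (0 to 7 and 0 to 3 leaving out each library), and after correction for GC content and length 10 rose and 1 fell. Of 13 mitochondrially encoded genes 2 rose and 0 fell, but after the correction 0 rose and 2 fell.

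No list of blood cell markers was called by camera with equal library weights over all 6 libraries, while fry called the stem and progenitor (adjusted p = 0.0215), B-lineage (0.0158) and myeloid markers (0.0134) as lower. As fry does not compare a list with other genes, its calls do not set these lists apart from them. For each of these 3 lists the adjusted p = 0.478 with an estimated correlation in camera. The B-lineage factor Pax5 lay at 0.0433 ± 0.0115 TPM (SD, n = 3) in both groups, and Ebf1 and Igll1 were at 0.09 TPM or less. Of 7 tested B-lineage markers 0 changed (limma, and 1 rise and 4 falls when adjusted over the list alone). Of 10 stem and progenitor regulators, with a median log2 fold change of −0.06, 3 fell and 0 rose, namely Runx1, from 30.0 ± 2.88 to 15.7 ± 1.14 TPM, Myb and Gfi1b. Of 9 myeloid markers 3 fell, including the granulocyte factor Cebpe, from 10.4 ± 3.02 to 3.31 ± 1.39 TPM. Of 16 erythroid and megakaryocyte markers 1 rose, the globin gene Hba-a2, which has a near-identical copy, and 4 fell, including Pf4 and Epor, and camera called that list with arrayWeights (adjusted p = 0.0356) and, with 7 falls, without TPR-FGFR1 replicate 3 (0.0445). Over all 6 libraries the adjusted p = 0.5 with an estimated correlation. Of 5 mast cell and basophil markers 1 rose. Of the T and NK cell markers only Nkg7 passed the filter and did not change, and no fibroblast or packaging-cell marker did, the highest being Tagln at 1.14 TPM. Of 20 chromatin regulators (camera adjusted p = 0.133, fry 0.016, and the adjusted p = 0.478 with an estimated correlation in camera) 1 rose, Ezh1, and 5 fell, including Dnmt3a, from 22.3 ± 0.863 to 16.0 ± 1.21 TPM. Leaving out each library in turn gave 0 to 10 falls for the chromatin regulators, 1 to 4 for the stem and progenitor regulators, 0 to 4 for the myeloid and 0 to 7 for the erythroid and megakaryocyte markers.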

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

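The correction for GC content and length and the fit of protein-coding genes alone were chosen after the data were seen; the other settings were chosen before. Genes changed at least 2-fold numbered 235, and 378 with a pseudocount of 0.1, 58 with a pseudocount of 5, 138 with no filter, 621 with arrayWeights (which stopped before convergence) and 136 after GC and length correction. Genes changed numbered 2600, and 1146 with no filter, 9281 with arrayWeights, 3986 after the correction and 4843 after the correction with TPR-FGFR1 replicate 3 left out. Leaving out each library gave 220 to 6396 changed genes and 85 to 551 at least 2-fold. Without empty vector replicates 1, 2 and 3 the counts were 406, 220 and 282, and without TPR-FGFR1 replicates 1, 2 and 3 they were 307, 869 and 6396. In the same order, 102, 90, 95, 85, 131 and 551 changed at least 2-fold. With the replicate block 764 genes changed; same-numbered libraries deviated from their group means with r = −0.193, −0.0750 and −0.153 over genes, none correlating best with its own number, so the numbers were not taken to pair samples. The Fgfr1 log2 fold change was 0.21 with a pseudocount of 5 (adjusted p = 0.0482, still called). It was 2.73 with a pseudocount of 0.1 (0.0587), 0.70 under quantile normalization (0.0716), 0.82 with a filter at 5 TPM (0.443), 0.82 with the replicate block (0.0935), and 0.66 to 0.92 leaving out each library, the call being lost in each of these last settings. The Tpr log2 fold change was −0.28 after GC and length correction (adjusted p = 0.00841) and −0.29 with replicate 3 also left out (0.00988), now past the threshold. Lists called numbered 7, and 11 with arrayWeights, 14 by fry and 0 by camera with an estimated correlation. After the correction with TPR-FGFR1 replicate 3 left out, Dusp2 log2 fold change (0.0482), Pim2 log2 fold change (0.0508) and Phlda3 log2 fold change (0.0837) changed sign. Over all settings and named genes, 1772 values kept their side of the threshold, 452 lost the call and 44 gained one. A further 3 changed sign with a call in the main fit or in that setting. Genes called in neither fit count among the 1772 even where their sign changed, as for Myc (−0.0888 to 0.138). The unfolded protein response, ATF4, interferon, DNA replication and ribosome biogenesis lists kept their camera calls at a correlation of 0.01 in all 20 settings; with an estimated correlation none was called. The causes of these differences were not tested. With depth unknown, no limit for genes of low level can be given.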

Other observations

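Gene families outside the fixed lists were looked at only because falls or rises had been seen among their members, so counts and values are given for them and no test. Of 6 replication-dependent histone genes, whose main transcripts end in a stem-loop and not a poly(A) tail, 4 fell and 0 rose, Hist2h2be falling from 6.27 ± 0.361 to 3.80 ± 0.497 TPM (SD, n = 3 per group). Both tested metallothionein genes, Mt1 and Mt2, fell, Mt1 from 249 ± 45.4 to 80.5 ± 48.1 TPM. Genes of protein entry into the endoplasmic reticulum and of its coated vesicles had 14 falls and 3 rises among 52, with a median log2 fold change of −0.14. Among them the translocon gene Sec61a1 fell from 217 ± 7.08 to 123 ± 16.0 TPM and Ddost from 96.1 ± 7.10 to 50.8 ± 6.11 TPM. Of 291 zinc finger genes named Zfp, 39 rose and 13 fell. Over all 12862 tested genes, for comparison with these families, 1309 rose and 1291 fell. After correction for GC content and length there were 5 falls among the histone genes, 20 falls and 5 rises among the secretory genes, and 51 rises and 28 falls among the Zfp genes. Over all 12541 genes in that fit, 2043 rose and 1943 fell.

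Within the stress groups, members chosen after their values were seen did not all move alike. Hspa5, the main chaperone of the endoplasmic reticulum, fell from 1268 ± 33.1 to 946 ± 99.1 TPM and Calr from 1373 ± 54.5 to 842 ± 78.3 TPM (SD, n = 3 per group), and Trib3 fell from 162 ± 12.2 to 89.2 ± 23.8 TPM. Atf4 itself stood at 256 ± 9.25 and 218 ± 7.73 TPM (adjusted p = 0.0617), Ddit3 at 191 ± 4.22 and 170 ± 24.7 TPM (0.267) and Asns at 271 ± 12.6 and 294 ± 23.8 TPM (0.360). Among replication genes Mcm2 fell from 45.8 ± 1.13 to 29.3 ± 6.59 TPM and Cdt1 from 41.3 ± 4.64 to 24.1 ± 6.53 TPM. Mecom, a member of the list of stem and progenitor regulators, was abundant in both groups, at 454 ± 26.9 and 528 ± 42.5 TPM (adjusted p = 0.13).

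In what follows, the GC tests, the test of empty vector RNA in library 3 and the alternatives using the GC correction were chosen only after the result was seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2600 changed genes, 235 of them at least 2-fold, against at most 3 in any other split, so it was 1 of 10 for both. It called 7 lists, as many as the highest of the others, so 3 of 10 splits gave as many. The other splits with 7 keep TPR-FGFR1 replicates 1 and 2 together.

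Genes that fell were richer in GC than genes that rose. GC and length trends as the whole cause of the changed genes were argued against. With the trends removed, 86.2% of called genes with a GC value were still called in the same direction. That share does not show how much of the GC pattern the trends make. A GC trend that differs between libraries of the same group was seen, as the difference between the highest and lowest of 5 GC bins spanned 0.791 log2 units over the TPR-FGFR1 libraries and 0.0999 over the empty vector libraries. An effect of the fusion common to its 3 libraries cannot be told apart from a technical trend in 2 of them, since the third showed a difference of only −0.0694. A difference in library preparation may therefore account for part of the GC pattern, and an effect of the fusion on part of it stays open.

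The falls of the unfolded protein response, ATF4 and interferon lists were set against the level, GC content and length of their members. None of 10000 matched random lists had a median as low for any of the 3 lists, which puts the share at 1e-04, the smallest they can give. Matched lists held 2.19, 3.88 and 2.18 falls on average where 14, 14 and 11 were seen. Their genes were drawn independently, so shares and p-values from matched lists do not allow for members moving together. Camera estimated correlations of 0.239, 0.286 and 0.0301 for the 3 lists. With the correlations of 0.239 and 0.286, the shares for the unfolded protein response and ATF4 lists cannot decide alone. After correction for GC content and length, the unfolded protein response list had a median of −0.61, with 15 falls. The correction brought the ATF4 median from −0.57 to −0.35, with 14 falls. It therefore did not remove these falls, but how much of the ATF4 fall comes from level, GC content and length stays open. Level, GC content and length are argued against as the whole cause for the interferon list. They are also argued against as the whole cause for ribosome biogenesis (median, two-sided adjusted p = 0.0168), where the estimated correlation was −0.00106. The antigen presentation (0.398) and NF-κB lists (0.834) did not differ from matched lists, and the MAPK feedback genes lay above theirs (0.0448). For DNA replication the median left this open (0.104), although 9 members fell against 2.86 on average in matched lists and 14 fell, with a median of −0.20, after correction for GC content and length. Camera still called 1 to 3 of the 3 lists in every other split, so its list calls alone do not set the real groups apart, and an effect of the fusion, or of a difference in culture such as selection or medium that the labels do not give for both groups, stays open and was not tested.

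TPR-FGFR1 replicate 3 lay between the groups on the first principal component (46.2% of the variance), at 0.408 of the way from the empty vector mean to replicates 1 and 2. Removing GC and length trends left it at 0.609, which does not decide whether such trends are the cause, as it lies between the values set for either answer. Empty vector RNA mixed into it would move rises and falls the same part of the way. Their medians, 0.641 over 64 genes and 0.546 over 131, differed by 0.0951 (bootstrap 95% interval −0.0850 to 0.201). A weaker response could do the same, so these medians cannot tell it from a mixture. Genes varied widely, with quartiles of 0.236 and 0.866 for rises and 0.357 and 0.830 for falls. The unfolded protein response list fell most in replicate 3 (median −0.72, against −0.53 and −0.50), while the ATF4 and interferon lists fell least there. Fgfr1, at 1.26 TPM, was highest in that library, which a mixture would lower, although it lies near the floor. A weaker response of that culture was not tested.

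The falls of Mt1 and Mt2 with the rise of Slc39a10 could come from lower activity of the zinc-sensing factor MTF1, a hypothesis under which its target Slc30a1 would fall. Slc30a1 had a log2 fold change of −0.0331 (95% interval −0.271 to 0.205), which by the bounds set beforehand counted against the hypothesis. After correction for GC content and length it was −0.157 (limma adjusted p = 0.11), a larger fall than those bounds allowed. Slc30a1 was not called lower in either fit. As only this target was read and the fits differ on the bound, the hypothesis stays open.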
